A study of Mus musculus with 16 samples.

How the data were processed

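Transcript levels were measured by RNA sequencing in epidermis isolated by heat shock from SKH-1 mice 8 to 12 weeks old. Control (K5Cre) and C/EBPβ knockout mice were either unexposed or sampled 6 h after 100 mJ/cm2 of UVB, with 4 libraries in each of 4 groups. Libraries were made with the NEBNext Ultra Directional kit per the labels, and whether the counting used strand is not stated. Per the submitters' processing notes the authors used FastQC, STAR, HTSeq and DESeq2, whose versions, and the genome build, are not given in the sources used here. The deposited table holds raw counts, whole numbers per Ensembl gene whose totals differ between libraries, and its 16 columns were joined to the samples by library number. The labels give 4 replicates per group but do not say which libraries are separate animals, so the p-values measure only the spread between these samples. Replicate numbers follow the order of the accessions and pair nothing. Xist and Y-linked counts placed 2 female and 2 male libraries in every group.

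Of 49585 genes in the table, 49326 had a symbol in GENCODE M21 (GRCm38), 259 had none, and 20578 had 0 counts throughout. Library totals were 33.0 to 53.3 M counts. The genes tested held at least 99.94% of the counts of every library, and the common biological coefficient of variation was 0.445. Between replicates the lowest chi-square per degree of freedom was 41.75 (genes with 20 or more counts), so replicates differed by more than counting error. Of the counts from 2 to 101, 68.8% were even, where 50% of those integers are even. The sources do not give the reason, and counting intervals, which treat each count as independent and cover counting error only, may be too narrow for this. Related genes such as the Krtap, Lce and Sprr families, and overlapping or antisense genes, have uncertain counts.

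The lists, tests, comparisons and naming rule were chosen before the data were examined. Counts were fitted with edgeR 4.0.16 in R 4.3.3: filterByExpr kept 17741 genes, TMM factors scaled the libraries, and a quasi-likelihood model with robust estimation and 1 mean per group was fitted to all 16 libraries. Two-sided F tests were adjusted by Benjamini-Hochberg over the tested genes, with a threshold of 0.05. The SE of a log2 fold change was its size over the square root of F. The comparisons were knockout against control unexposed and after UVB, UVB against unexposed in each genotype, and the difference between the 2 UVB responses. Gene lists were tested with camera (limma 3.58.1, two-sided, preset correlation 0.01), adjusted over the lists with 5 or more tested members. Members were also counted when adjusted over the list alone. Tables and figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

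The 33 lists were type I interferon response, interferon genes and receptors, nucleic acid sensing, p53 targets, apoptosis regulators, nucleotide excision repair, cell cycle, immediate early and AP-1, C/EBP family, inflammatory cytokines, stress, basal, spinous and granular or cornified keratinocyte genes, NRF2 targets, unfolded protein response, heat shock, lipid synthesis, hair follicle, circadian clock, mitochondrial transcripts, and markers of Langerhans cells, T cells, neutrophils, monocytes, mast cells, melanocytes, fibroblasts, endothelium, skeletal muscle, adipocytes, erythroid cells and Schwann cells. The mast cell, adipocyte and erythroid lists had too few tested members for camera, which left 30. Some genes stood in more than 1 list, so the lists were not independent of each other. Named genes were fixed ones (Cebpb, Cebpa, Cebpd, Trp53, Cdkn1a, Mdm2, Irf7, Isg15, Ifnb1, Ifnk and 1 that is not reported here), up to 6 per direction with the largest changes, a mean of at least 1 CPM and no overlap between the groups, and up to 4 members of a list with the smallest p. Other named genes are said to have been chosen after their values were seen. For a group with 0 counts a fold is given as at least its value against a floor of 3 counts per library, and for 1 to 3 counts as a ratio with a 95% counting interval. Where leaving out a library left a group with 0 counts, the fitted log2 fold change is given instead. Its size then rests on the model rather than on counts in that group.

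Each tool was tested on simulated data with 200 changed genes among 17741, beside a changed p53 list. The 200 were drawn from genes with a mean of at least 1 CPM, so recovery of weaker genes was not measured. In the order of the comparisons above, edgeR recovered 49, 49, 62, 56 and 27 of 100 genes changed 2-fold, and 88, 78, 80, 85 and 70 of 100 changed 4-fold. It called 2, 9, 4, 5 and 4 of the unchanged genes, and none with the wrong sign. DESeq2 called 42, 41, 28, 36 and 25 of the unchanged genes, and limma voom 3, 5, 5, 2 and 5. A p53 list doubled in the simulation gave camera adjusted p-values of 1.07e-63, 9.13e-65, 6.2e-72, 7.45e-69 and 4.47e-43, and 1, 2, 1, 0 and 0 unchanged lists were called. Simulated genes were drawn independently, whereas members of real lists were correlated (estimated 0.367 and 0.403 for the interferon list in the 2 knockout comparisons). These list counts therefore do not give the error rate of camera on the real data. Alternatives were DESeq2 1.42.0, limma voom with library weights, RLE and upper-quartile scaling, 2 other count filters, fits with only the compared groups, 2 stricter thresholds, camera with an estimated correlation, fry, and leaving out each library in turn. Alternatives chosen after the data were seen were a sex term, keeping a single exposed control library, and leaving out 3 libraries rich in Gm42418. A library kept alone was assumed to vary like the other groups. No column of the table was left out.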

Results

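RNA sequencing measured transcript levels in the epidermis of SKH-1 mice, a hairless stock used in work on ultraviolet skin damage. The design crossed an epidermal deletion of C/EBPβ with exposure to ultraviolet B (UVB). C/EBPβ, encoded by Cebpb, is a basic leucine zipper transcription factor made by keratinocytes, the main cells of the epidermis. Mice labelled K5Cre were the controls, and mice labelled as lacking C/EBPβ are called knockout here. Epidermis came from mice 8 to 12 weeks old, either unexposed or 6 h after 100 mJ/cm2 of UVB, with 4 libraries in each of the 4 groups. The 16 libraries held 33.0 to 53.3 M counts each. The first principal component held 30.2% of the variance and the second 14.8%. Across genes, the correlation between pairs of libraries of one group was 0.954 to 0.965 in unexposed controls, 0.944 to 0.971 in unexposed knockouts, 0.906 to 0.934 in exposed controls and 0.951 to 0.971 in exposed knockouts, where genes are not independent replicates. Counted at equal depth, exposed control libraries 1 to 4 held 17562, 19306, 17007 and 18095 detected genes, against 19202 to 21505 in the exposed knockout libraries.

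The targeted gene was examined first in every library. Cebpb (ENSMUSG00000056501) has a single exon on chromosome 2, from 167688915 to 167690418 of GRCm38. Its level was 166 ± 13.7 CPM (counts scaled by library size, mean ± SD, n = 4) in unexposed control epidermis and 291 ± 28.6 CPM (n = 4) in exposed control epidermis. Knockout epidermis held 0.574 ± 0.297 CPM (n = 4) unexposed and 1.93 ± 1.07 CPM (n = 4) after UVB. The 4 unexposed control libraries read 186, 160, 164 and 155 CPM and the 4 exposed ones 253, 305, 286 and 320 CPM, whereas the highest of the 8 knockout libraries read 3.03 CPM. Cebpb fell by 8.22 on the log2 scale in unexposed knockout epidermis (SE 0.49, edgeR adjusted p = 9.93e-07) and by 7.23 after UVB (SE 0.45, adjusted p = 1.71e-06). Its log2 difference after UVB was 0.81 in controls (SE 0.34, edgeR adjusted p = 0.0805, DESeq2 adjusted p = 0.0351), so this call depended on the tool. In knockouts the remaining signal rose by 1.80 (SE 0.43, adjusted p = 0.00513). The difference between these UVB responses was 0.99 (SE 0.55, adjusted p = 0.893). An exon of Tmem189 on the opposite strand, at 167689511 to 167689822, lies inside the Cebpb exon, and Tmem189 was lower in knockout epidermis by 3.46 unexposed (log2 fold change -3.46, SE 0.32, adjusted p = 2.26e-06) and by 2.54 after UVB (-2.54, SE 0.30, adjusted p = 7.21e-05). Tmem189 was chosen after its values were seen, and reads of the 2 genes cannot be told apart where they overlap unless the counting used strand.

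**Figure D1:**
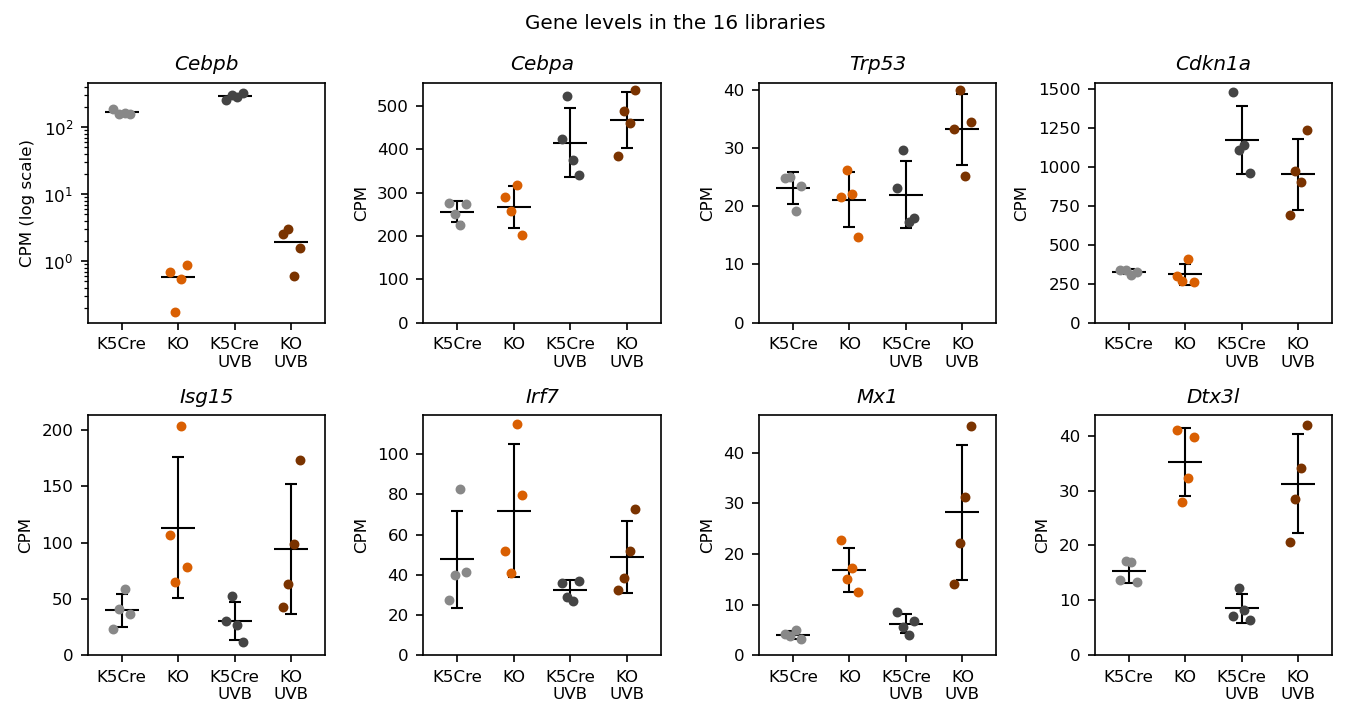
CPM of 8 genes in each of the 16 libraries, by group, with a log scale for Cebpb and linear scales for the other genes, 1 point per library, and lines for the mean and (except Cebpb) the SD of n = 4. Cebpb lay at 155 CPM or more in every control library and at 3.03 CPM or less in every knockout library, and Mx1 averaged 3.99 CPM in unexposed controls against 16.8 CPM in unexposed knockouts.

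The first comparison asked what loss of C/EBPβ changed in epidermis that had not been irradiated. Of 74 interferon-stimulated genes tested, 25 rose in knockout epidermis, and the list was not called with an estimated correlation (adjusted p = 0.0849). Mx1, an antiviral GTPase, rose 4.23-fold (log2 fold change 2.08, SE 0.31, adjusted p = 0.000714), the secreted glycoprotein gene Lgals3bp rose 3.43-fold (SE 0.32, adjusted p = 0.00495), the ubiquitin ligase gene Dtx3l rose by 1.20 (SE 0.22, adjusted p = 0.00495), and Cgas, which senses cytosolic DNA, rose 1.80-fold (SE 0.15, adjusted p = 0.00322). Ercc1, a nucleotide excision repair gene, rose 2.84-fold (log2 fold change 1.51, SE 0.13, adjusted p = 9.93e-07). The epithelial mucin gene Muc16 rose 21.9-fold (SE 0.94, adjusted p = 0.0155) and the small proline-rich gene Sprr2f 7.95-fold (SE 0.53, adjusted p = 0.0127). Without control library 4 Muc16 was 47.5-fold higher. Cebpb aside, the largest falls among the named genes were in keratin-associated protein genes, which belong to the hair shaft. Krtap19-2 was 165-fold lower (log2 fold change -7.36, SE 0.94, adjusted p = 0.000312). Krtap19-4 had 617 counts in the 4 control libraries against 1 in the knockouts (ratio 700, 95% counting interval 125 to 27700). Krtap19-2 was 315-fold lower without knockout library 4. Of 17741 genes tested, 171 rose and 202 fell at an adjusted p under 0.05, and with upper-quartile scaling 180 rose and 136 fell.

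Of 74 tested members of the type I interferon response list, 25 rose, 0 fell and 49 did not pass, and 56 rose when adjusted over the list alone. The 25 became 12, 14, 10 and 8 without control library 1, 2, 3 and 4, and 10 and 15 without knockout library 1 and 2. The list median was 1.36, camera gave an adjusted p of 5.72e-45, and adjusted p = 0.0849 with an estimated correlation. Fry gave the list an adjusted p of 0.0074. These rises stood beside a difference in gene detection. At equal depth knockout libraries 1 to 3 had 20540 to 21136 genes with a count and the controls 18475 to 19940. Knockout library 4 had 18802, with 10.2% mitochondrial and 7.52% Gm42418 counts. Its mean log2 CPM over the list was 2.72, against 3.23 to 3.98 in the other knockouts and 1.53 to 1.95 in the controls. Isg15 and Irf7 were 2.85-fold (adjusted p = 0.231) and 1.51-fold (adjusted p = 0.6) higher in the mean and did not pass. The series title names this response and p53, so the direction of either list is not independent evidence. Ifnb1, which encodes interferon beta, had 0 counts in unexposed controls and 20 in unexposed knockouts, all in 1 library, and Ifnk had 0 in every group, so neither was tested. No interferon gene of the interferon and receptor list passed the count filter, so its 6 tested members were all receptor genes. They gave 0 calls (Il10rb -0.64, adjusted p = 0.156, camera adjusted p = 0.326). In the nucleic acid sensing list 1 of 19 members rose, which was Cgas, and 7 rose when adjusted over the list alone (camera adjusted p = 6.47e-05, and adjusted p = 0.0849 with an estimated correlation). Adar was 1.55-fold higher (adjusted p = 0.0534) and Zbp1 6.71-fold (adjusted p = 0.058), without passing. Cgas, Adar and Zbp1 also belong to the interferon list, so these lists are not separate evidence. Markers of Langerhans cells, the resident antigen-presenting cells of the epidermis, moved beside these genes: 4 of 13 rose, 0 fell, and 7 rose when adjusted over the list alone (median 0.71, camera adjusted p = 4.25e-09, and adjusted p = 0.0849 with an estimated correlation). Mfge8 rose 2.11-fold (SE 0.21, adjusted p = 0.00917), and this call ended without control library 4 (adjusted p = 0.0511). Without that library 0 of the 13 Langerhans genes were called, and 2, 1, 1 and 1 without control library 1 or 3 and knockout library 1 or 2.

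Keratinocyte genes of several layers differed as well. Of 26 stress keratinocyte genes, which mark wounded or inflamed epidermis, 7 rose and 0 fell, and 13 rose and 1 fell when adjusted over the list alone (median 1.11, camera adjusted p = 1.41e-11, and adjusted p = 0.0988 with an estimated correlation). Vegfa, the vascular growth factor gene, rose 2.76-fold (SE 0.24, adjusted p = 0.00284), and Hbegf 2.21-fold (SE 0.23, adjusted p = 0.0143). The Hbegf call ended without control library 3 or 4 (adjusted p up to 0.0642). In the basal keratinocyte list 3 of 16 rose and 9 rose when adjusted over the list alone (camera adjusted p = 7.39e-08, and adjusted p = 0.0849 with an estimated correlation). The integrin gene Itga3 rose 1.64-fold (SE 0.15, adjusted p = 0.0129). It was lost without control library 4 (adjusted p = 0.0514). Without that library 0 of 16 basal genes were called, and without control library 1 or 2 or knockout library 2 only 1 was. The granular and cornified layer list had 1 member that rose and 3 that fell of 29, and 5 and 8 when adjusted over the list alone (median -0.22, camera adjusted p = 0.0081, and adjusted p = 0.447 with an estimated correlation). Cnfn rose by 0.68 on the log2 scale (adjusted p = 0.0133). Its call ended without control library 4 or knockout library 1 (adjusted p up to 0.0685). Lce1b, a late cornified envelope gene, was 1.82-fold lower (adjusted p = 0.00907). The call did not hold without control library 3 (adjusted p = 0.0551). The 15 spinous genes gave 0 calls (Krtdap -0.52, adjusted p = 0.078, camera adjusted p = 0.11). Of 23 hair follicle genes 0 passed (median -1.33, Krt75 -1.78, adjusted p = 0.089, camera adjusted p = 0.0229, and adjusted p = 0.651 with an estimated correlation).

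Among the transcription factor and signalling lists, 3 of 25 immediate early and AP-1 genes rose and 0 fell, and 5 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.0583). Atf3, a stress-induced AP-1 partner, rose 4.41-fold (SE 0.38, adjusted p = 0.0079), and 2.93-fold without knockout library 1. In the C/EBP family list Cebpb fell and the other 5 members did not pass, with Cebpa at 0.06 (SE 0.15, adjusted p = 0.976) and Cebpd at 0.21 (SE 0.27, adjusted p = 0.903). That list had a median of 0.12, a mean of -1.23 and a downward test (camera adjusted p = 0.0194, and adjusted p = 0.0849 with an estimated correlation). Of 25 inflammatory cytokine genes 2 rose and 2 fell, and 3 and 4 when adjusted over the list alone (camera adjusted p = 0.518), with the cytokine gene Il24 higher by 4.44 (SE 0.84, adjusted p = 0.00636). The only control library with Il24 counts was library 4 (0.091 CPM), and the fit without it gave 7.84. Without knockout library 1 it was 3.58. Of 40 p53 targets 1 rose, 1 fell and 38 did not pass, the same numbers as adjusted over the list alone (median -0.03 with TMM and 0.01 with upper-quartile scaling, camera adjusted p = 0.534). Gadd45a, a growth arrest gene, was 2.15-fold lower (SE 0.17, adjusted p = 0.00114), and Ak1, which encodes adenylate kinase, rose 2.78-fold (SE 0.29, adjusted p = 0.01). Trp53 (-0.13, SE 0.20, adjusted p = 0.935), Cdkn1a (-0.08, SE 0.18, adjusted p = 0.961) and Mdm2 (-0.01, SE 0.15, adjusted p = 0.995) did not pass. The 29 apoptosis regulators gave 0 calls (camera adjusted p = 0.909), and Ercc1 was the 1 call among 29 nucleotide excision repair genes (camera adjusted p = 0.623).

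Of 10 fibroblast markers 1 rose, with Postn, which encodes the matrix protein periostin, 3.86-fold higher (SE 0.33, adjusted p = 0.00571, camera adjusted p = 0.000326, and adjusted p = 0.0849 with an estimated correlation). Neutrophil markers (2 of 6 rose, 3 when adjusted over the list alone, median 1.67, or 1.39 with genes at 0 counts set to their bound) gave a camera adjusted p of 0.000183, and adjusted p = 0.0849 with an estimated correlation. Flt1, which rose 2.43-fold (adjusted p = 0.0176), was the 1 call among 5 endothelial markers (camera adjusted p = 0.0477, and adjusted p = 0.131 with an estimated correlation), and it ended without control library 3 or 4 or knockout library 1 (adjusted p up to 0.07). Lists with 0 members past the test included T cells (median -0.54, camera adjusted p = 0.00803, and adjusted p = 0.38 with an estimated correlation), monocytes and macrophages (0.56, camera adjusted p = 0.0421, and adjusted p = 0.138 with an estimated correlation) and melanocytes (-0.88, camera adjusted p = 0.0477, and adjusted p = 0.485 with an estimated correlation). The cell cycle list (median 0.28, camera adjusted p = 0.00939, and adjusted p = 0.447 with an estimated correlation) and the circadian clock list (-0.27, camera adjusted p = 0.0148, and adjusted p = 0.0849 with an estimated correlation) also had 0. In the lipid synthesis list 2 of 21 fell, the same when adjusted over the list alone (camera adjusted p = 3.62e-07, and adjusted p = 0.221 with an estimated correlation). The NRF2 (1 call), unfolded protein, heat shock, skeletal muscle, Schwann cell and mitochondrial lists were not called (camera adjusted p = 0.479, 0.058, 0.778, 0.68, 0.75 and 0.0974). Median, mean and test differed in sign for the apoptosis, excision repair, heat shock and Schwann cell lists as well as the C/EBP list. Leaving out control library 2, 3 or 4 or knockout library 1 or 2 lowered the count of 373 genes to 225, 144, 134, 148 and 168, while DESeq2 called 798 and limma voom 1474.

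The second comparison asked how knockout and control epidermis differed after irradiation, the contrast closest to the series title. Of the 74 interferon-stimulated genes 50 rose in knockout epidermis (adjusted p = 0.0322 for the list with an estimated correlation). Cmpk2, an interferon-induced nucleotide kinase gene, had 0 counts in all 4 exposed control libraries and 4.34 ± 3.51 CPM (n = 4) in exposed knockouts, at least 50-fold higher against a floor of 3 counts per library, and at least 30.7-fold without exposed knockout library 4. The antiviral genes Ifi44 and Rsad2 rose 54.6-fold (SE 1.15 on the log2 scale, adjusted p = 0.0128) and 36.5-fold (SE 1.05, adjusted p = 0.0156), and Rnf213, Dtx3l, Mx1 and Sp100 rose 4.79-fold (adjusted p = 7.21e-05), 3.66-fold (adjusted p = 7.3e-05), 4.54-fold (adjusted p = 0.00033) and 5.24-fold (adjusted p = 0.000397). Ifi44 had counts in only 1 exposed control library, library 2 (0.778 CPM), and its log2 fold change of 5.77 was 12.06 without it. Without that library Rsad2 was 65.3-fold higher. The hepcidin gene Hamp2 rose by 9.31 (SE 1.79, adjusted p = 0.0124) and the neuropeptide gene Npy by 6.39 (SE 1.18, adjusted p = 0.00352). Npy too had counts only in exposed control library 2 (0.137 CPM), and gave 10.28 without it, while Hamp2 gave 11.72 without exposed control library 1 and 8.59 without exposed knockout library 1. Lower in knockouts were Sgpp2, a sphingosine phosphate phosphatase gene, by 16.5-fold (log2 fold change -4.04, SE 0.37, adjusted p = 5.83e-06), the anticoagulant receptor gene Thbd by 27.1-fold (-4.76, SE 0.74, adjusted p = 0.00217), and Krtap19-2 by 67.9-fold (-6.08, SE 0.84, adjusted p = 0.000419). Thbd was 16.9-fold lower without exposed control library 2. Ercc1 rose 2.99-fold (SE 0.13, adjusted p = 9.3e-07). In all, 418 genes rose and 412 fell.

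In the type I interferon list 50 of 74 members rose, 0 fell and 24 did not pass, and 64 rose when adjusted over the list alone (median 2.13, camera adjusted p = 7.61e-58, and adjusted p = 0.0322 with an estimated correlation). Isg15 was 3.13-fold (adjusted p = 0.111) and Irf7 1.52-fold (adjusted p = 0.389) higher without passing. Beside this list, exposed control libraries 1, 3 and 4 held fewer detected genes than any exposed knockout library, and in the 4 exposed controls 5.24% to 9.65% of the counts were mitochondrial against 5.44% to 5.99%. Of 19 nucleic acid sensing genes 4 rose, and 8 when adjusted over the list alone (camera adjusted p = 4.91e-06, and adjusted p = 0.0561 with an estimated correlation), among them the RNA editing gene Adar (1.87-fold, adjusted p = 0.00365), Cgas (1.64-fold, adjusted p = 0.00747) and the RNA sensor gene Ddx58 (2.21-fold, adjusted p = 0.0131). Adar, Cgas and Ddx58 are members of the interferon list too, so their rises are not a separate signal. The 6 tested receptor genes of the interferon and receptor list gave 0 calls, and 2 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.529). Ifnb1 had 0 counts in exposed controls and 16 in exposed knockouts. Of the Langerhans markers 6 of 13 rose, and 12 when adjusted over the list alone (median 0.81, camera adjusted p = 1.67e-07, and adjusted p = 0.151 with an estimated correlation). The 6 became 1 and 1 without exposed control library 1 and 4, and 3 and 0 without exposed knockout library 1 and 2. The integrin gene Itgax rose 2.09-fold (adjusted p = 0.0195). It was lost without exposed control library 4 or exposed knockout library 2 (adjusted p up to 0.0794).

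The p53 target list gave 1 rise and 2 falls in 40 members, the same when adjusted over the list alone (median -0.15, camera adjusted p = 0.00854, and adjusted p = 0.35 with an estimated correlation). Trp53 itself was 1.51-fold higher (SE 0.20, adjusted p = 0.0827), Cdkn1a was at -0.30 (SE 0.18, adjusted p = 0.352) and Mdm2 at -0.26 (SE 0.15, adjusted p = 0.337). Eda2r, a receptor gene, was 2.17-fold lower (adjusted p = 0.0292). Its call ended without exposed control library 1 or exposed knockout library 1, 2 or 3 (adjusted p up to 0.111). Of 29 apoptosis regulators 2 rose and 1 fell, and the median was -0.01, the mean 0.15 and the test downward (camera adjusted p = 0.986). Ercc1 was the 1 call among the excision repair genes (camera adjusted p = 0.091). In the cell cycle list 2 of 41 rose, the same when adjusted over the list alone (median 0.51, camera adjusted p = 0.000349, and adjusted p = 0.35 with an estimated correlation). The proliferation marker Mki67 rose 1.76-fold (SE 0.18, adjusted p = 0.0106). The AP-1 list had 2 falls of 25, the same when adjusted over the list alone (camera adjusted p = 0.00854, and adjusted p = 0.505 with an estimated correlation): the phosphatase gene Dusp5 was 1.55-fold lower (adjusted p = 0.00835) and Jund 1.41-fold lower (adjusted p = 0.0111). Cebpg rose 1.56-fold (SE 0.12, adjusted p = 0.00268), while Cebpa was at 0.17 (adjusted p = 0.598) and Cebpd at 0.16 (adjusted p = 0.801), and the C/EBP list had a median of 0.02, a mean of -1.13 and a downward test (camera adjusted p = 0.0175, and adjusted p = 0.0859 with an estimated correlation). Of 25 cytokine genes 1 rose and 3 fell, and 4 and 5 when adjusted over the list alone (camera adjusted p = 0.796). The falls included the interleukin 36 gene Il1f6 (2.10-fold lower, adjusted p = 0.000412) and Il1f5 (1.57-fold lower, adjusted p = 0.0111), which encodes the interleukin 36 receptor antagonist.

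Some basal genes rose and some cornified layer genes fell in exposed knockout epidermis. In the basal list 7 of 16 rose and 0 fell, and 13 rose and 1 fell when adjusted over the list alone (median 0.62, camera adjusted p = 4.39e-09, and adjusted p = 0.0561 with an estimated correlation). Itga3 rose 1.98-fold (SE 0.15, adjusted p = 0.000599), the hemidesmosome genes Col17a1 1.59-fold (adjusted p = 0.00428) and Itgb4 by 0.59 on the log2 scale (adjusted p = 0.00747), and Krt5 2.20-fold (adjusted p = 0.00641). Of 29 granular and cornified genes 0 rose and 7 fell, and 15 fell when adjusted over the list alone (median -0.46, camera adjusted p = 7.37e-11, and adjusted p = 0.0801 with an estimated correlation), with the loricrin gene Lor 1.87-fold lower (SE 0.20, adjusted p = 0.0105) and Lce1b 1.76-fold lower (SE 0.17, adjusted p = 0.00865). The stress keratinocyte list had 1 rise and 2 falls of 26, and 1 and 5 when adjusted over the list alone (median -0.15, camera adjusted p = 0.0822), the rise being Vegfa (2.17-fold, adjusted p = 0.0111). Of the spinous genes 1 of 15 fell (camera adjusted p = 0.27), and Krt79 was the 1 hair follicle gene that rose (1.99-fold, adjusted p = 0.00987, camera adjusted p = 0.609). The metallothionein genes Mt2 and Mt1 rose 2.56-fold (adjusted p = 0.00643) and 2.39-fold (adjusted p = 0.0104) within an NRF2 list that was not called (3 of 18 rose, camera adjusted p = 0.251). The lipid synthesis list had 2 falls of 21, the same when adjusted over the list alone (camera adjusted p = 0.000349, and adjusted p = 0.451 with an estimated correlation). The clock list had 2 falls of 15, the same when adjusted over the list alone (median -0.47, camera adjusted p = 5.1e-05, and adjusted p = 0.0161 with an estimated correlation), with the output gene Tef at -0.59 on the log2 scale (adjusted p = 0.0148). The call did not hold without exposed knockout library 2 or 3 (adjusted p up to 0.0523).

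Postn and Fap, fibroblast markers that keratinocytes or other cells can also make, rose 3.87-fold (adjusted p = 0.00363) and 3.29-fold (adjusted p = 0.0124) in 10 fibroblast genes (camera adjusted p = 0.0402, and adjusted p = 0.35 with an estimated correlation), and Flt1 rose 2.86-fold (adjusted p = 0.00363) in an endothelial list whose median was -0.53 and mean 0.04 (camera adjusted p = 0.929). The 13 mitochondrial transcripts had 0 calls and a median of -0.80 (camera adjusted p = 7.76e-06, and adjusted p = 0.35 with an estimated correlation). Neutrophil (1 rise of 6), monocyte (1 rise of 10), T cell, melanocyte, skeletal muscle, Schwann cell, heat shock (1 fall) and unfolded protein lists were not called (camera adjusted p = 0.0908, 0.252, 0.252, 0.091, 0.796, 0.796, 0.529 and 0.11). The mast cell, adipocyte and erythroid lists had fewer than 5 tested members: Hdc was at 0.67 (SE 1.02) and Kit at 0.19 (SE 0.80), Fabp4 at -0.89 (SE 0.76), Plin4 at 0.17 (SE 1.08) and Cidec at -2.48 (SE 1.76), and Hba-a1 at 1.40 (SE 1.15), Hbb-bs at -0.62 (SE 1.27) and Alas2 at -0.75 (SE 0.90). Lpl, the lipoprotein lipase gene, was 4.95-fold lower (SE 0.54, adjusted p = 0.0217). This call ended without exposed knockout library 2, 3 or 4 (adjusted p up to 0.0805). Of the genes that passed in unexposed epidermis, 96 rose and 123 fell again after UVB, where independent lists would share 4 and 4.7, and 151 of the 171 rises and 198 of the 202 falls kept their sign. The count of 830 genes became 1356 without exposed control library 2, 529 without exposed control library 3, and 492, 419 and 520 without exposed knockout library 1, 2 and 3, and DESeq2 called 1654. With only exposed control library 1, 2, 3 or 4 kept of the 4, an alternative chosen after the data were seen, the counts were 938, 154, 1505 and 516. In such fits the library kept is assumed to vary like the other groups.

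**Figure D2:**
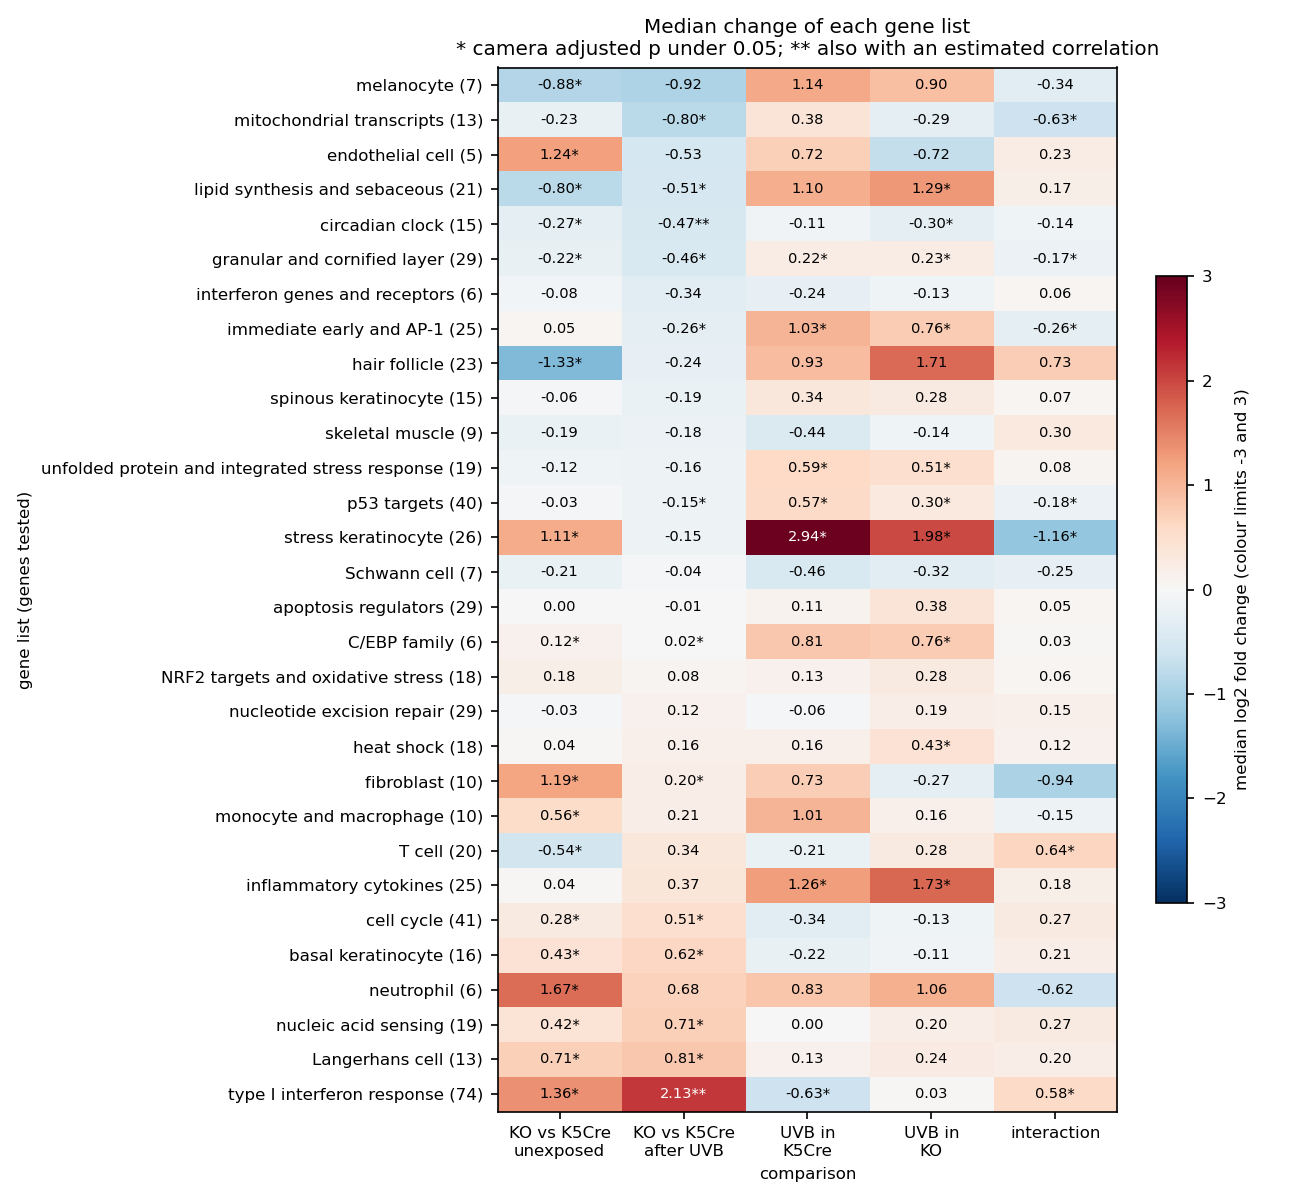
Median log2 fold change (colour and printed value) of the 30 tested gene lists, 1 per line with its number of tested genes, in the 5 comparisons (columns), where an asterisk marks a camera adjusted p under 0.05. The interferon list had medians of 1.36 and 2.13 in knockout against control epidermis, and the stress keratinocyte list 2.94 and 1.98 after UVB.

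A block of 17 tested Krtap genes on chromosome 16, from 88818667 to 89420111 of GRCm38, had 9 falls and 0 rises unexposed and 9 falls and 0 rises after UVB, with medians of -3.92 and -3.87 under TMM scaling and -3.87 and -3.86 under upper-quartile scaling. This block was chosen after its values were seen. The 9 unexposed falls became 2, 3, 3 and 2 without control library 1, 2, 3 and 4, and 2, 2 and 3 without knockout library 1, 2 and 3. The 9 after UVB became 4 and 3 without exposed control library 1 and 3, and 4, 3, 4 and 5 without exposed knockout library 1, 2, 3 and 4. Tested Krtap genes of chromosome 16 outside the block did not pass. They ranged from -3.88 (Krtap26-1) to 0.02 (Krtap27-1) unexposed, and from -1.3 (Krtap8-1) to 0.74 (Krtap27-1) after UVB. The edges of the block were chosen with it and were not tested. Hair keratins and Tchh, which are made in the same follicles, had 0 calls among 11 genes (medians -1.35 and -0.41), and the Krtap genes of chromosome 11 had 0 calls among 22 (medians -1.32 and -0.84). The mean log2 CPM of the block less that of the hair keratins was lower in knockouts by 3.42 unexposed (log2 difference -3.42) and by 3.15 after UVB (-3.15), without a test because the block was chosen for its fall. Krtap20-2 was 18.2-fold lower after UVB (SE 0.85, adjusted p = 0.00939), and 29-fold lower without exposed knockout library 2. Members of this family have near-identical relatives, so counts of single members are uncertain.

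**Figure D3:**
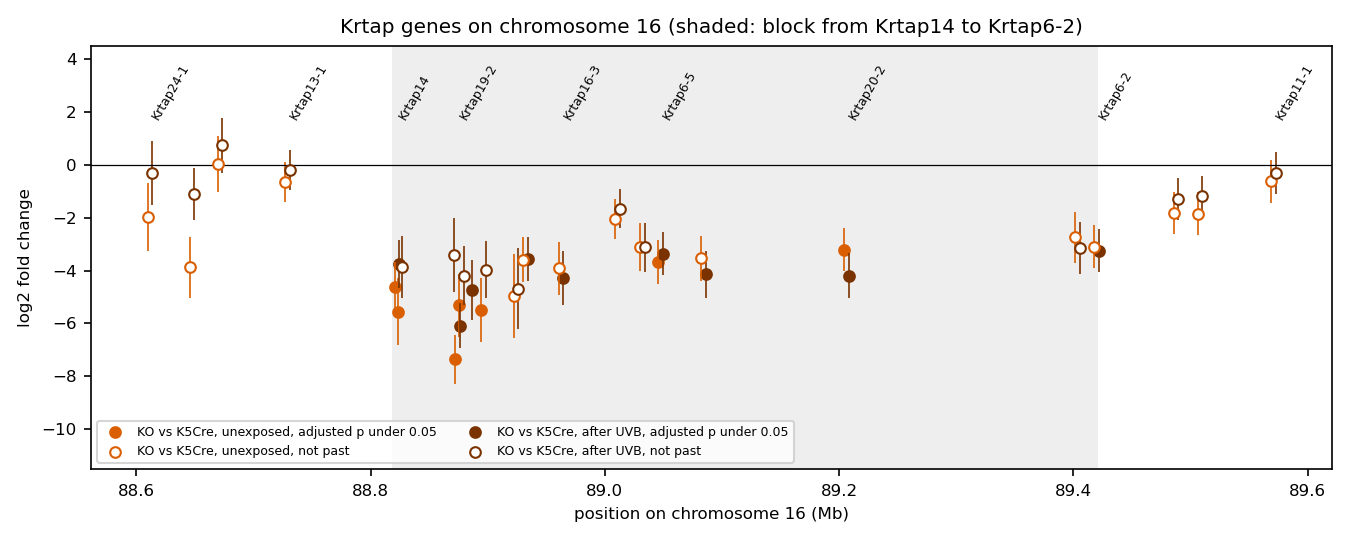
Log2 fold change of knockout against control (y axis) for tested Krtap genes by position on chromosome 16 of GRCm38 (x axis, megabases), unexposed and after UVB, with error bars of 1 SE and genes of 3 counts or fewer in a compared group left out. The block from 88818667 to 89420111 had medians of -3.92 and -3.87.

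The third comparison described the response of control epidermis to UVB. Several p53 targets rose 6 h after exposure: Cdkn1a, the cell cycle inhibitor p21 gene, rose 3.58-fold (log2 fold change 1.84, SE 0.18, adjusted p = 1.78e-07), the p53 ligase gene Mdm2 rose 2.80-fold (SE 0.15, adjusted p = 2.87e-07), Ccng1 4.93-fold (SE 0.22, adjusted p = 1.98e-07) and the pro-apoptotic gene Pmaip1 16.2-fold (SE 0.39, adjusted p = 1.7e-06). Trp53 did not pass (-0.07, SE 0.20, adjusted p = 0.815). The AP-1 gene Fosl1 rose 49.5-fold (SE 0.33, adjusted p = 2.5e-09), and the cornified envelope genes Lce3d and Sprr2h rose 216-fold (SE 0.70, adjusted p = 2.86e-06) and 23.8-fold (SE 0.32, adjusted p = 1.24e-08). Trem1, Sprr3, Pip5kl1 and Cmtm2b had 0 counts in the unexposed control libraries and were at least 40.2-fold, 35.3-fold, 29.5-fold and 29.1-fold higher after UVB, against a floor of 3 counts per library. Without exposed control library 3 the bound for Pip5kl1 was 17.6-fold. Vgf, a neuropeptide precursor gene, went from 1 to 691 counts (ratio 860, 95% counting interval 154 to 34000). Pdzd7, Adprhl1 and Zfp984 were 80.0-fold (adjusted p = 0.00031), 76.5-fold (adjusted p = 4.53e-05) and 35.7-fold (adjusted p = 9.36e-06) lower. Pdzd7 had counts in only 1 exposed control library, library 2, and its log2 fold change of -6.32 was -10.25 without it. Adprhl1 had counts only in library 1, and its -6.26 was -9.76 without it. Zfp984 was 76.1-fold lower without library 4. The test called 3146 rises and 3197 falls.

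Among the lists, 23 of 26 stress keratinocyte genes rose and 0 fell, the same when adjusted over the list alone (median 2.94). Camera gave this list adjusted p = 3.7e-21, or 0.18 with an estimated correlation, and fry adjusted p = 9.86e-06. The rises included the growth factor genes Hbegf (7.58-fold, adjusted p = 8.07e-08) and Areg (7.02-fold, adjusted p = 9.45e-07). Of 25 AP-1 genes 21 rose and 0 fell, the same when adjusted over the list alone (camera adjusted p = 3.16e-12, and adjusted p = 0.225 with an estimated correlation). Junb rose 2.52-fold (adjusted p = 7.78e-07). Of 40 p53 targets 17 rose and 5 fell, 18 and 5 when adjusted over the list alone (median 0.57, camera adjusted p = 0.000493, and adjusted p = 0.231 with an estimated correlation). Fry gave the p53 list adjusted p = 8.81e-05. Cytokine genes gave 14 rises and 1 fall of 25, the same when adjusted over the list alone (camera adjusted p = 1.35e-05, and adjusted p = 0.225 with an estimated correlation). The chemokine gene Ccl20 rose 4.73-fold (adjusted p = 9.19e-07) and Il1b 12.8-fold (adjusted p = 6.44e-06). In the cornified list 13 rose and 5 fell of 29, 14 and 6 when adjusted over the list alone (camera adjusted p = 0.000183, and adjusted p = 0.462 with an estimated correlation). Sprr1a rose 19.0-fold (adjusted p = 3.66e-08) and Cnfn 4.24-fold (adjusted p = 2.72e-09). The unfolded protein list had 10 rises and 1 fall of 19, 10 and 3 when adjusted over the list alone (camera adjusted p = 0.000772, and adjusted p = 0.263 with an estimated correlation). The chaperone gene Dnajb9 rose 7.82-fold (adjusted p = 1.32e-09) and Hspa5 3.08-fold (adjusted p = 2.03e-07).

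The interferon list gave 2 rises and 23 falls of 74 in controls after UVB, 2 and 22 when adjusted over the list alone (median -0.63, camera adjusted p = 0.0258, and adjusted p = 0.828 with an estimated correlation). Rnf213 was 3.42-fold lower (adjusted p = 2.36e-05), the immunoproteasome gene Psmb9 2.04-fold lower (adjusted p = 0.000759), Cmpk2 was at least 17.4-fold lower (at least 10.5-fold without unexposed control library 3), and the exonuclease gene Isg20 rose 7.69-fold (adjusted p = 8.8e-08). Isg15 (-0.39, adjusted p = 0.626) and Irf7 (-0.57, adjusted p = 0.258) did not pass. These falls stood beside the low gene detection of exposed control libraries 1, 3 and 4, and the list's call ended without exposed control library 4 (adjusted p = 0.112), with limma voom (adjusted p = 0.0876) and without the 3 libraries rich in Gm42418 (adjusted p = 0.142). With only library 2 of the 4 kept, and assumed to vary like the other groups, it had adjusted p = 0.852. Cebpa rose 1.62-fold (adjusted p = 0.00125) and Cebpd 2.21-fold (adjusted p = 0.00213) in a C/EBP list that was not called (4 rises and 1 fall of 6, camera adjusted p = 0.0511). The receptor gene Ifnlr1 was 2.26-fold lower (adjusted p = 2.26e-05, list camera adjusted p = 0.306). The heat shock list was not called (7 rises and 1 fall of 18, camera adjusted p = 0.0753), although Hsp90aa1 rose 8.32-fold (adjusted p = 4.25e-09), nor were the apoptosis, excision repair, cell cycle, basal and clock lists (camera adjusted p = 0.199, 0.861, 0.386, 0.202 and 0.306). In those lists Ercc1 rose 2.41-fold (adjusted p = 2.31e-07), the damage recognition gene Xpa was 2.50-fold lower (adjusted p = 3.38e-05), Krt15 was 3.92-fold lower (adjusted p = 1.57e-05) and Dbp, a clock output gene, fell by 2.20 (adjusted p = 8.05e-07). Among cell markers Cd68 rose 5.77-fold (adjusted p = 2.66e-08) and Fap was 8.30-fold lower (adjusted p = 4.79e-06), with no marker list called by camera. Fry called the monocyte list (adjusted p = 0.00804) and the neutrophil list (adjusted p = 0.0317). Median, mean and test differed in sign for excision repair, Langerhans and fibroblast genes.

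The fourth comparison described the UVB response of knockout epidermis. Cdkn1a rose 3.08-fold (log2 fold change 1.62, SE 0.18, adjusted p = 1.23e-06), Mdm2 2.36-fold (SE 0.15, adjusted p = 3.54e-06), Ccng1 5.03-fold (SE 0.22, adjusted p = 3.3e-07) and Pmaip1 9.69-fold (SE 0.38, adjusted p = 1.13e-05). Trp53 rose 1.57-fold (SE 0.20, adjusted p = 0.0137). It was lost without unexposed knockout library 4 or exposed knockout library 2 or 4 (adjusted p up to 0.087). Fosl1 rose 15.4-fold (adjusted p = 8.32e-08), the prostaglandin synthase gene Ptgs2 51.9-fold (adjusted p = 7.73e-06), Sprr3 347-fold (adjusted p = 4.03e-06) and the gastrokine gene Gkn1 274-fold (adjusted p = 6.93e-06). Unexposed knockout library 2 held all the unexposed counts of Sprr3 and Gkn1 in knockouts, and their log2 fold changes of 8.44 and 8.10 were 11.95 and 11.08 without it. Ptgs2 rose 105-fold without unexposed knockout library 1. Cdhr2 went from 1 to 1039 counts (ratio 1020, 95% counting interval 182 to 40100), and Lrrc10b from 1 to 482 (ratio 471, 84.1 to 18600). Cyp26b1, a retinoic acid hydroxylase gene, was 7.09-fold lower (adjusted p = 2.78e-05), the leucine-rich repeat gene Flrt1 10.2-fold lower (adjusted p = 0.000109) and the T cell checkpoint gene Ctla4 7.72-fold lower (adjusted p = 0.00985). The test called 3207 rises and 2503 falls. Of the calls in the 2 genotypes, 2521 rises and 1992 falls were shared, where independent lists would share 568.7 and 451.1, and the 2 sets of libraries had no library in common.

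The stress list rose in 20 of 26 members, 21 when adjusted over the list alone (median 1.98, camera adjusted p = 3.38e-11, and adjusted p = 0.224 with an estimated correlation). Sprr2h rose 11.6-fold (adjusted p = 2.42e-07) and the defensin gene Defb3 21.3-fold (adjusted p = 4.05e-05). AP-1 genes gave 15 rises of 25, 16 when adjusted over the list alone (camera adjusted p = 4.64e-07, and adjusted p = 0.256 with an estimated correlation), and cytokine genes 13 of 25, the same when adjusted over the list alone (camera adjusted p = 2.88e-06, and adjusted p = 0.216 with an estimated correlation). Ccl20 rose 6.60-fold (adjusted p = 2.27e-07). Of 40 p53 targets 16 rose and 4 fell, the same when adjusted over the list alone (median 0.30, camera adjusted p = 0.0143, and adjusted p = 0.443 with an estimated correlation), a call that ended with limma voom (adjusted p = 0.0733) and with the CPM filter (adjusted p = 0.0507). The unfolded protein list gave 9 rises and 1 fall of 19, 11 and 1 when adjusted over the list alone (camera adjusted p = 0.000377, and adjusted p = 0.224 with an estimated correlation), and the heat shock list 8 and 1 of 18, 9 and 1 when adjusted over the list alone (camera adjusted p = 0.0103, and adjusted p = 0.452 with an estimated correlation). Dnajb9 rose 8.63-fold (adjusted p = 3.46e-09) and Hsp90aa1 6.23-fold (adjusted p = 4.16e-08). The C/EBP list had 5 rises of 6, the same when adjusted over the list alone (camera adjusted p = 0.0321, and adjusted p = 0.216 with an estimated correlation). Cebpa rose 1.75-fold (adjusted p = 0.000346) and Cebpd 2.14-fold (adjusted p = 0.00303).

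Clock genes gave 1 rise and 5 falls of 15 in knockouts after UVB, 2 and 6 when adjusted over the list alone (camera adjusted p = 0.0293, and adjusted p = 0.216 with an estimated correlation), with Dbp 4.75-fold lower (adjusted p = 1.06e-06) and Tef 2.35-fold lower (adjusted p = 1.22e-06). In the cornified list 13 rose and 6 fell of 29, the same when adjusted over the list alone (camera adjusted p = 0.0321, and adjusted p = 0.777 with an estimated correlation). Sprr1a rose 10.6-fold (adjusted p = 4.84e-07). Lipid genes had 7 rises and 2 falls of 21, 13 and 2 when adjusted over the list alone (camera adjusted p = 0.0321, and adjusted p = 0.804 with an estimated correlation). The interferon list gave 4 rises and 2 falls of 74, 2 and 0 when adjusted over the list alone, with a median of 0.03 under TMM and -0.05 under upper-quartile scaling (camera adjusted p = 0.993). Isg20 rose 4.10-fold (adjusted p = 5.81e-06) and the helicase gene Helz2 2.65-fold (adjusted p = 0.00273), while Isg15 (-0.26, adjusted p = 0.778) and Irf7 (-0.56, adjusted p = 0.286) did not pass. Ercc1 rose 2.53-fold (adjusted p = 2.27e-07) in an excision repair list that was not called (camera adjusted p = 0.439). Tie1, an endothelial receptor gene with 0 counts in unexposed knockouts, was at least 11-fold higher. Cd68 rose 5.18-fold (adjusted p = 1.1e-07), with no marker list called by camera. Fry called the monocyte list (adjusted p = 0.00834). Median, mean and test differed in sign for the cell cycle, endothelial and skeletal muscle lists.

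The last comparison tested whether the response to UVB differed between the genotypes. At an adjusted p under 0.05 edgeR called 0 of 17741 genes, with 0.114 as the smallest adjusted p. At an unadjusted p under 0.05, edgeR gave 1043 genes, DESeq2 1409 and limma voom 1228, and after adjustment DESeq2 called 52 and limma voom 0. On simulated data DESeq2 called 25 unchanged genes in this comparison, and edgeR 4. The differences of response, which did not pass, were 1.32 for Rnf213 (SE 0.36, adjusted p = 0.571), 0.13 for Isg15 (SE 0.76, adjusted p = 0.995), -0.22 for Cdkn1a (SE 0.25, adjusted p = 0.947), 0.72 for Trp53 (SE 0.28, adjusted p = 0.783), -1.69 for Fosl1 (SE 0.39, adjusted p = 0.504), -2.20 for Atf3 (SE 0.52, adjusted p = 0.504), -1.36 for Hbegf (SE 0.33, adjusted p = 0.504) and -2.84 for Lce3a (SE 0.65, adjusted p = 0.504).

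Over whole lists, camera called 7 differences of response, and 0 with an estimated correlation or with fry. The stress keratinocyte list had a median of -1.16 (1 higher and 7 lower when adjusted over the list alone, camera adjusted p = 1.5e-18, and adjusted p = 0.234 with an estimated correlation), with Sprr2f at -3.12 (SE 0.70, adjusted p = 0.504) and Sprr2e at -2.73 (SE 0.59, adjusted p = 0.504). The AP-1 list had -0.26 (0 and 2 when adjusted over the list alone, camera adjusted p = 1.06e-06, and adjusted p = 0.385 with an estimated correlation), the cornified list -0.17 (0 and 3 when adjusted over the list alone, camera adjusted p = 8.88e-06, and adjusted p = 0.385 with an estimated correlation) and the p53 list -0.18 (0 when adjusted over the list alone, camera adjusted p = 0.046, and adjusted p = 0.633 with an estimated correlation). The interferon list had 0.58 (1 and 0 when adjusted over the list alone, camera adjusted p = 1.43e-07, and adjusted p = 0.633 with an estimated correlation), T cell markers 0.64, with Cd3g at 1.06 (SE 0.37, adjusted p = 0.765, list camera adjusted p = 0.000115, and adjusted p = 0.385 with an estimated correlation), and mitochondrial transcripts -0.63 (camera adjusted p = 0.00145, and adjusted p = 0.732 with an estimated correlation). The exposed control libraries, which enter all of these differences, had the mitochondrial share and gene detection given above. The interferon difference ended with limma voom (adjusted p = 0.0709) and had adjusted p = 0.588 with only exposed control library 2 kept, which was then assumed to vary like the other groups, and the p53 difference ended in 8 of the 16 fits that left out a single library (adjusted p up to 0.277). Median, mean and test differed in sign for the C/EBP, cytokine, unfolded protein and endothelial lists.

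**Figure D4:**
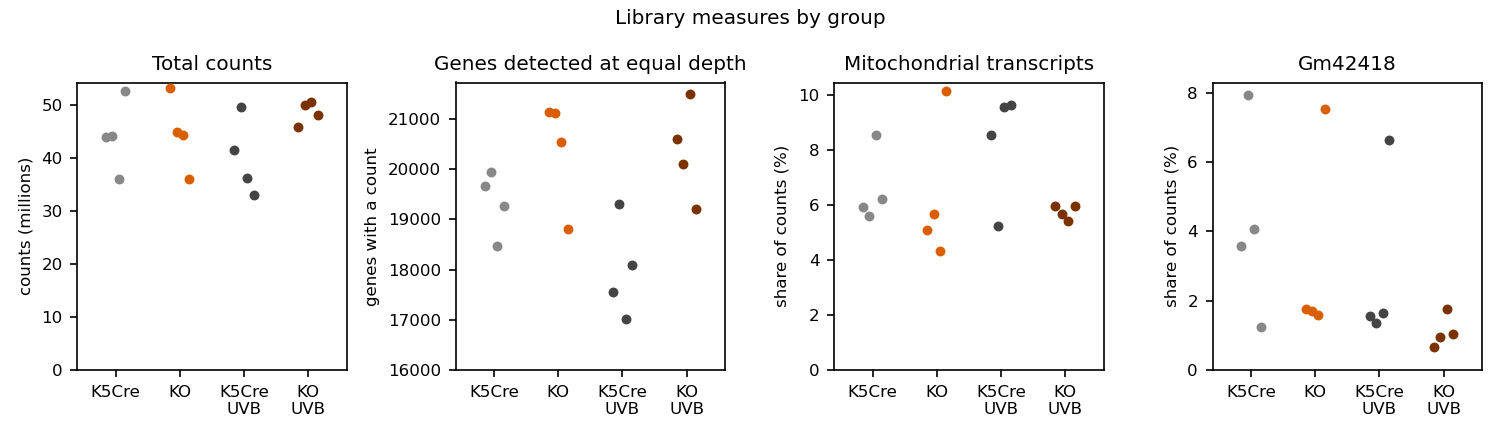
Measures of each of the 16 libraries by group, with 1 point per library. Genes detected at equal depth ranged from 17007 to 19306 in exposed controls and from 19202 to 21505 in exposed knockouts.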

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

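The tests of the patterns below were chosen after the results were seen, and the regrouping tests were written after the first counts were seen but before any regrouping was run. All 35 regroupings of the libraries into 4 and 4 were run for each of 4 comparisons. The real grouping called 373, 830, 6343 and 5710 genes, and the highest of the other 34 regroupings called 2, 33, 2 and 1. So 1 of 35 reached the real count each time, the smallest share that 35 regroupings can give. Chance is thus an unlikely source of these calls but is not excluded, and the share was not adjusted over the patterns tested. For the difference between UVB responses the real count was 0 (edgeR, against 52 with DESeq2, which called 25 unchanged genes on simulated data, 0 with limma voom and 1043 genes at an unadjusted p under 0.05), which any regrouping reaches (100 of 100), so this says nothing about chance. The 3 regroupings with the most calls (63, 19 and 6) kept the unexposed libraries grouped by genotype, as did 4 others that called 0. Such a regrouping keeps the genotype difference of the unexposed libraries but not that of the exposed ones. The effect of genotype then enters the tested difference, so these regroupings are no clean reference for it. The number of lists called was less safe. For unexposed epidermis 1 of 35 regroupings reached 17 lists (highest other 13), but after UVB 2 of 35 reached 13 (highest other 13). For the UVB responses 17 of 35 reached 7 (11) and 8 of 35 reached 10 (14), and for their difference 61 of 100 reached 7 (15). Chance is not made unlikely for the last 4 of these counts. For the difference the regroupings cannot decide, because the effect of genotype enters them.

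Interferon-stimulated genes were higher in knockout epidermis: 25 of 74 members passed unexposed, 8 without control library 4, and 50 after UVB. With an estimated correlation camera gave the list adjusted p = 0.0849 unexposed and 0.0322 after UVB. For the list median 1 of 35 regroupings reached the real value in both conditions (1.36 against a highest other of 1.09, and 2.13 against 1.67). That is the smallest share possible, so chance was unlikely but not excluded. Low gene detection in 3 of the 4 exposed control libraries could lower any list there. High detection in 3 of the 4 unexposed knockout libraries could raise any. The highest median among 10000 random lists of like expression was 0.4 against 2.13 after UVB and 0.29 against 1.36 unexposed. Both tests argue against a shift of all genes of like expression as the whole cause. Random lists hold unrelated genes, so neither test can decide on a shift shared by a correlated list. The first of these tests replaced one with only exposed control library 2 kept, whose median was 1.77 with 2 members called, against 2.28, 2.38 and 2.7 with 28, 33 and 30 called for libraries 1, 3 and 4, so the number of calls rests on the libraries of low detection. More Langerhans cells might carry the signal, but interferon less Langerhans score was higher in knockouts by 1.91 after UVB and by 0.9 unexposed. Higher interferon signalling in knockout epidermis is a hypothesis, and other causes, such as a difference in strain or housing, were not tested.

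The Krtap block of chromosome 16 was lower in knockouts, and fewer hair follicle cells could lower it too. The block less the hair keratins stood at -3.15 after UVB, so the block fell further than these keratins did. Because the block was chosen for its fall, this gap cannot decide whether fewer follicle cells were the cause. Reads moved between Krtap genes of chromosome 16 would keep their total, but relative to the other Krtap genes it was lower in knockouts by 0.98 after UVB (-0.98) and in every library of both conditions. Reads moved to Krtap genes of other chromosomes remain open, as the total of all Krtap genes less the hair keratins differed by -0.63 after UVB with overlapping libraries. A genetic difference near the block between the mouse stocks was not tested and remains open.

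The stress keratinocyte list rose less with UVB in knockouts (-1.16) by camera, but not with an estimated correlation (adjusted p = 0.234) or fry (adjusted p = 0.423), and 0 of its members passed. Low gene detection would lower exposed controls and so move the difference upward, the opposite of its direction, and 10000 random lists of like expression, which only give a spread, had a lowest median of -0.29. An earlier test, with only exposed control library 2 kept, gave -1.28, against -1.37, -1.24 and -0.68 for libraries 1, 3 and 4. A higher starting level with a like level after UVB matched the values, since knockout less control was 1.11 unexposed and -0.15 after UVB. These 2 values are the parts of the difference itself and were seen beforehand. They describe where the difference lay and support no cause.

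By Dixon's test 8 of 108 groups of 4 held an outlying library, where chance gives about 1 in 20, or 5.4, for continuous values. A group with counts in only 1 library always passes, as for Sprr3, Cmtm2b and Ifnb1, and a group at 0 throughout never can. The 5.4 does not hold for such groups, so the 8 cannot be judged against it. The share of counts in Gm42418 was 7.52% in unexposed knockout library 4 (others 1.58% to 1.76%) and 6.64% in exposed control library 4 (1.37% to 1.66%), and even counts were 66.3% in exposed control library 2 (75.6% to 76.7%). The libraries of the other groups had 62.25% to 69.73% even counts. Exposed control library 2 lay within that range, whereas exposed control libraries 1, 3 and 4, those of low gene detection, lay above it. The interferon score was 1.53 in unexposed control library 4 (1.88 to 1.95). Single libraries held all the signal of Sprr3 (0.106 CPM, unexposed knockout library 2) and Cmtm2b (0.277 CPM, unexposed knockout library 1), and Ifnb1 had 20 counts in unexposed knockout library 1 and 16 in exposed knockout library 3. The UVB responses of the genotypes differed by camera for 7 lists, against 0 with an estimated correlation, 0 with fry and 0 genes in edgeR: interferon 0.58, p53 targets -0.18, AP-1 -0.26, stress keratinocyte -1.16, cornified layer -0.17, T cell 0.64 and mitochondrial transcripts -0.63. With only exposed control library 1, 2, 3 or 4 kept, the interferon difference was 0.7, 0.14, 0.85 and 1.11.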

How the results depend on the processing

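The sex term, the fits with a single exposed control library and the fit without 3 libraries rich in Gm42418 were chosen after the data were seen, the other alternatives before. The cause of a change was not tested. No call of the counts, lists and genes rerun here reversed. Medians near 0 did change sign: the p53 list unexposed from -0.03 to 0.01 with upper-quartile scaling, the interferon list for UVB in knockouts from 0.03 to -0.05, and the stress list after UVB from -0.15 to 0.01 and 0.22 with library 3 or 4 alone. Upper-quartile scaling gave 180 rises and 136 falls in unexposed knockouts, against 171 and 202. At an adjusted p under 0.01 the 2 knockout comparisons called 109 and 240 genes, and with at least a doubling or halving the 4 pairwise comparisons called 194, 376, 2935 and 2322. DESeq2 called 798, 1654 and, for the difference of UVB responses, 52 genes, limma voom 1474 unexposed, and no count filter gave 2 for the difference. A library kept alone was assumed to vary like the other groups. Exposed control library 2, 3 or 4 alone gave 154, 1505 and 516 genes after UVB, library 4 alone 2989 for UVB in controls, and libraries 1 to 4 alone 247, 1, 570 and 27 for the difference. With an estimated correlation camera called 0, 2, 0, 0 and 0 of 30 lists, against 17, 13, 7, 10 and 7. Fry called 12, 10, 14, 15 and 0, and camera after the CPM filter called 5 for UVB in knockouts. By fry the interferon list passed in knockouts against controls, unexposed (adjusted p = 0.0074) and after UVB (adjusted p = 0.000389). The stress list passed by fry for UVB in controls (adjusted p = 9.86e-06) and knockouts (adjusted p = 9.8e-05), but not for the difference (adjusted p = 0.423). The p53 list passed by fry for the same 2 UVB responses (adjusted p = 8.81e-05 and 0.000507). The interferon list had adjusted p = 0.0849 (unexposed), 0.828 (UVB in controls) and 0.633 (difference) with an estimated correlation, 0.0922 and 0.441 with fry, and 0.0876 and 0.0709 with limma voom for the last 2. Library 2 alone gave it 0.852 and 0.588, and leaving out the Gm42418-rich libraries 0.142 for UVB in controls. The p53 list had 0.35, 0.231, 0.443 and 0.633 with an estimated correlation (after UVB, UVB in controls, UVB in knockouts, difference), 0.106 and 0.633 with fry (after UVB, difference), and 0.0507 with the CPM filter and 0.0733 with limma voom for UVB in knockouts. Library 3 or 4 alone gave it 0.122 and 0.472 after UVB, and library 2, 3 or 4 alone 0.109, 0.311 and 0.544 for the difference. Leaving out 1 library at a time gave 134 to 435, 419 to 1356, 5520 to 6501, 4625 to 5474 and 0 to 2 genes. Counts moved by more than 1.5 times without unexposed control library 2 (225), 3 (144) or 4 (134) and unexposed knockout library 1 (148) or 2 (168), without exposed control library 2 (1356) or 3 (529) and exposed knockout library 1 (492), 2 (419) or 3 (520), and for the difference without exposed control library 4 (1) and exposed knockout library 1 (1) or 4 (2). Lists ranged over 15 to 19, 12 to 17, 7 to 8, 9 to 11 and 6 to 10. The interferon list ranged over 3.6e-51 to 1.31e-37, 5.88e-79 to 1.08e-46, 0.000974 to 0.112 (ended without exposed control library 4), 0.394 to 0.836 and 4.16e-15 to 0.00259. The p53 list ranged over 0.214 to 0.846, 0.000174 to 0.0466, 0.000193 to 0.000954, 0.0031 to 0.0208 and 0.00147 to 0.277, the last ended without unexposed control library 1 (0.0893) or 2 (0.16), unexposed knockout library 3 (0.277), exposed control library 1 (0.156) or 2 (0.0684), and exposed knockout library 1 (0.139), 2 (0.172) or 3 (0.0749). Cebpb ranged over -8.42 to -7.89 and -7.54 to -6.93. Of the named genes called, 32 of 47, 31 of 68, 13 of 112 and 13 of 105 lost their call in 1 or more of these fits, and 0 reversed. No paired analysis was possible because the labels carry no pairing.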

Other observations

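The 2 genes below were chosen after their values were seen. They neighbour Cebpb on chromosome 2, and both were higher in knockout epidermis: Prex1, a Rac exchange factor gene, by 1.40 unexposed (SE 0.26, adjusted p = 0.00604) and 0.92 after UVB (SE 0.26, adjusted p = 0.044), and 1200007C13Rik by 1.76 (SE 0.27, adjusted p = 0.00121) and 1.15 (SE 0.26, adjusted p = 0.0131). Of 26 tested genes within 1 Mb that do not overlap Cebpb, these 2 rose and 0 fell unexposed, while 4 rose and 1, Atp9a (-0.66, SE 0.13, adjusted p = 0.00601), fell after UVB. The source of these rises, such as the altered locus or flanking strain sequence, was not tested.

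Ercc1 rose in all 4 pairwise comparisons, by 1.51 and 1.58 with loss of C/EBPβ (adjusted p = 9.93e-07 and 9.3e-07) and by 1.27 and 1.34 with UVB (adjusted p = 2.31e-07 and 2.27e-07). Across genes, log2 fold changes of knockout against control correlated between unexposed and exposed epidermis (r = 0.338), and those of UVB between controls and knockouts (r = 0.633), where genes are not independent replicates and neither pair shares a library.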
